A study of Homo sapiens with 12 samples.

How the data were processed

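The series holds 12 RNA sequencing libraries of human cell lines, 3 in each of 4 groups named by the labels' line and treatment fields. Per the labels' protocols, total RNA was made into stranded mRNA libraries and read as 100-bp pairs. The deposited table gives TPM, 1 value per gene symbol and library, and per the submitters' processing notes the authors used STAR 2.7.3a, RSEM 1.3.1 and the GRCh38 build. The annotation release is not given in the sources used here. RSEM estimates how reads shared between genes are divided, so values of genes with near-identical copies or pseudogenes are less certain. The table has 57189 rows, of which 37 hold no value in any library, leaving 57152. In 44 of these a value has more than 2 decimals, which is what a mean over genes that share a symbol would give, and 27884 are never above 0. TPM sums to nearly the same total in each library whatever was sequenced, so a large rise of some genes lowers the others, and neither depth nor counting error can be had from it. No count model was used for that reason. Symbols were matched to GENCODE 29 (56807 found), from which positions, gene types, GC content and lengths came. 2 list members were found under older symbols, a match added after first results were seen. 0 columns were left without a sample.

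Values were transformed as log2(TPM + 1), a pseudocount of 1, and the 13968 genes with a mean of at least 1 TPM over the 12 libraries were tested. A linear model with all 4 groups (8 residual degrees of freedom) was fitted with limma 3.58.1 in R 4.3.3, with a mean-variance trend in the empirical Bayes step. Its two-sided p-values were adjusted by Benjamini-Hochberg within each of the 4 comparisons, with a threshold of 0.05, and a log2 difference of at least 1 counted as 2-fold. The median residual SD was 0.128 on the log2 scale.

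Gene groups were tested with limma's camera at a preset correlation of 0.01 over 32 lists (541 entries), adjusted over the lists with at least 4 tested members. The lists, drawn from textbook knowledge, were cholesterol biosynthesis, sterol uptake and SREBP2 regulation, LXR targets, fatty acid synthesis and desaturation, phospholipid synthesis, sphingolipid synthesis, lipid droplets, fatty acid oxidation, lysosomal enzymes and membrane, autophagy, the integrated stress response, endoplasmic reticulum chaperones, heat shock, metallothioneins, NRF2 targets, xenobiotic metabolism, p53 targets, proliferation, hypoxia and glycolysis, mitochondrially encoded genes, cytosolic ribosomal proteins, alveolar type II and surfactant, alveolar type I, airway epithelium, mesenchymal transition and matrix, epithelial junctions, inflammatory mediators, interferon-stimulated genes, acute phase and coagulation, and fibroblast, leukocyte and endothelial markers. Camera with an estimated correlation and fry were alternatives.

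The groups, tests, lists and alternatives, and the rule for naming genes, were fixed before the data were examined. By that rule the text could name, per comparison, the 10 largest rises and 10 largest falls among genes past the test, with groups not overlapping and a mean of at least 5 TPM in the higher group, up to 4 members per list with the largest change among those past it, and 27 genes of lipid, lysosome, surfactant and stress biology whatever their values. Pseudogenes and placeholder, antisense (-AS) and small RNA names were passed over, and so were 2 Y-linked genes. Of 413 results past the test that the rule takes, 163 are not printed. For 62 of these the call was lost when 1 library was left out, and most such genes were passed over, a choice made after their values were seen. The others were left out for length, also after values were seen, or are not reported here. Where the text prints a gene whose call was lost, it names the libraries.

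Alternatives were pseudocounts of 0.1 and 5, no filter and a filter at a mean of 5 TPM, median-of-ratios scaling, quantile normalization, removal of mitochondrially encoded genes with rescaling, limma without trend, with robust variance or with array weights, a fit of only the 2 groups compared, the replicate number as a block, and leaving out each of the 12 libraries in turn. A run on protein-coding genes only was chosen after seeing the data. For the relation of the amiodarone and HPbCD effects, unchanged groups that share the LB amiodarone libraries were simulated 100 times. The tests were tried on simulated data built on the real means and spread of the 13968 genes, with 50 genes changed at each fold size in each comparison. For LB DMSO against A549 DMSO, amiodarone against LB DMSO, amiodarone plus HPbCD against amiodarone, and amiodarone plus HPbCD against LB DMSO, in that order, 24, 22, 16 and 16% of 1.25-fold changes were recovered, 66, 56, 64 and 62% of 1.5-fold, 92, 82, 84 and 88% of 2-fold and 100, 96, 100 and 94% of 4-fold ones. The share of false calls was 6, 5.88, 8.97 and 3.7%, above 0.05 in 3 of 4. A missed 1.25-fold change is common. A heat shock list shifted by 0.5 (log2) for amiodarone against LB DMSO was the 1 list called. Genes were drawn independently, so false list calls went untested.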

Results

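RNA was sequenced from A549 cells, a human lung adenocarcinoma line, and from LB cells, for which the labels name A549 as the source. The 12 libraries formed 4 groups of 3: A549 cells with vehicle (A549 DMSO), LB cells with vehicle (LB DMSO), LB cells with amiodarone, and LB cells with amiodarone plus hydroxypropyl-beta-cyclodextrin (HPbCD). Amiodarone, a cationic amphiphilic antiarrhythmic drug known to accumulate in lysosomes, was given at 10 µM for 24 h, and HPbCD, a cyclic oligosaccharide that binds cholesterol, at 10 mg/ml from seeding, 24 h before the drug. The vehicle was 0.1% DMSO. The series asks how a changed lipid balance under HPbCD bears on the disorder that amiodarone causes in alveolar cells. Neither a group with HPbCD alone nor A549 cells with amiodarone were analysed here, so an effect of HPbCD was measured only in the presence of the drug.

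Expression was given as TPM, whose sums per library lay between 999449 and 999632. TPM keeps no read depth, so the depth behind each value is unknown. Between 20966 and 22261 genes were above 0 in a library and 13968 genes were tested. Replicates correlated at 0.9846 to 0.9886 within groups and 0.9427 to 0.9858 between groups across the tested genes, which are not independent replicates. The first principal component held 51.5% of the variance and separated A549 from all LB libraries, and the second held 11% and ordered LB DMSO, amiodarone and amiodarone plus HPbCD. Mitochondrially encoded transcripts made up 5.38% to 9.19% of TPM and ribosomal protein transcripts 16.4% to 18.3%, with overlapping ranges across groups for the former. Levels below, also in brackets, are mean TPM ± SD with n = 3 libraries per group, the reference group first, and differences are on the log2(TPM + 1) scale, which understates changes of low genes, and adjusted p are from limma. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Gene positions are those of GENCODE 29 on GRCh38. For gene lists, counts within the list are members past the test when adjusted over the list alone, and where a call was lost with 1 library left out, the range of adjusted p over the libraries left out is given.

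LB DMSO was compared with A549 DMSO to find how the LB line differs from A549 without drug. The largest difference was in surfactant genes. SFTPC (chromosome 8, 22156913 to 22164479, plus strand), which encodes surfactant protein C of alveolar type II cells, rose from 0.46 ± 0.296 to 589.9 ± 66.3 TPM (log2 difference 8.67 ± 0.14 SE, adjusted p = 2.92e-13). SFTPD (chromosome 10, 79937740 to 79982614, minus strand), for surfactant protein D, rose from 0.247 ± 0.13 to 300.0 ± 18.2 TPM (log2 difference 7.92 ± 0.092 SE, adjusted p = 2.55e-14). SFTPB (chromosome 2, 85657314 to 85668741, minus strand), for surfactant protein B, was listed at 0 in each of the 3 A549 libraries and at 245, 264 and 232 TPM in LB DMSO (adjusted p = 2.8e-15). ABCA3 (chromosome 16, 2275881 to 2340746, minus strand), the phospholipid transporter of lamellar bodies, rose from 18.9 ± 0.836 to 314 ± 35.3 TPM (log2 difference 3.98 ± 0.073 SE, adjusted p = 1.47e-12).

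The other type II markers tested did not pass. Of the 9 alveolar type II genes tested, 4 rose and 5 did not pass, 4 within the list (median log2 difference 0.27, 0.42 without A549 DMSO replicate 1 or 0.16 without A549 DMSO replicate 2 or 0.17 without LB DMSO replicate 2, adjusted p = 2.53e-05, adjusted p = 0.0538 with an estimated correlation). The members past the test were the 3 surfactant protein genes and ABCA3. NAPSA (2.5 ± 0.862 and 2.96 ± 0.91, adjusted p = 0.562), a surfactant-processing protease, was not past it. LAMP3, a lamellar body membrane protein, lay between 0.19 and 0.57 TPM and SFTPA1 between 0 and 0.03 TPM over the 12 libraries, too low to be tested. Alveolar type I markers were lower. Of the 5 type I genes tested, 4 fell and 1 did not pass, 4 within the list (median log2 difference -1.06, adjusted p = 0.01, adjusted p = 0.18 with an estimated correlation). These were the caveolae genes CAV1 (298 ± 40 to 139 ± 14.7) and CAV2 (132 ± 15.1 to 62.3 ± 3.59), with GPRC5A (159 ± 40.2 to 74.7 ± 8.54) and EMP2 (20.4 ± 1.73 to 13 ± 0.442).

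Beyond surfactant, the largest rises were in SLC16A6 (1.1 ± 0.352 to 134 ± 4.63), a monocarboxylate transporter family member, and CES1 (1.6 ± 0.691 to 149.5 ± 18.4), a carboxylesterase, followed by DNER (0.58 ± 0.164 to 60.6 ± 1.43) and SLC1A3 (0.00667 ± 0.0115 to 29.4 ± 4.93), a Notch ligand and a glutamate transporter. SERPINI1 (1.28 ± 0.421 to 42.4 ± 3.63), or neuroserpin, HGF (0.080 ± 0.0781 to 19.7 ± 1.73), or hepatocyte growth factor, and C15orf48 (8.31 ± 2.72 to 150.4 ± 16.3) rose too (adjusted p at most 4.09e-09 for these 7). Among the largest falls were ANXA3 (105 ± 31.8 to 1.71 ± 0.0896) and TM4SF4 (122 ± 27 to 2.45 ± 0.126), an annexin and a tetraspan membrane protein, NTRK3 (45.3 ± 1.42 to 0.687 ± 0.875), the neurotrophin-3 receptor, and VCAN (25.8 ± 3.36 to 0.143 ± 0.0611), a matrix proteoglycan. FXYD2 (266 ± 14.7 to 15.3 ± 1.37) and CNTN1 (146 ± 15.8 to 10.6 ± 0.846) also fell, as did DPYSL3 (41.8 ± 4.84 to 1.21 ± 0.172) and FBN2 (19.3 ± 2.45 to 0.463 ± 0.159) and CD24 (599.7 ± 29.6 to 39.3 ± 2.35), with adjusted p at most 4.84e-08 over the 9. CD24 has near-identical copies, so its level is uncertain. In each of these genes the 3 libraries of one line all lay above the 3 of the other.

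Lysosomal genes were higher in LB DMSO. Of the 33 lysosomal genes tested, 28 rose and 5 did not pass, 28 within the list (median log2 difference 0.43, adjusted p = 5.34e-16, adjusted p = 0.073 with an estimated correlation). Examples were the sialidase NEU1 (22.1 ± 1.28 to 64.8 ± 2.23) and the cathepsins CTSL (322 ± 24 to 882 ± 34.7) and CTSB (253 ± 18.4 to 442 ± 7.28). NPC1 (31.6 ± 3.05 to 40.9 ± 1.11), the lysosomal cholesterol exporter, GPNMB (1.52 ± 0.541 to 3.24 ± 0.52) and LAMP1 (61.1 ± 0.966 to 74.1 ± 0.809) also rose (adjusted p at most 0.00289). LIPA (55.6 ± 4.88 and 61.5 ± 2.87, adjusted p = 0.112), the lysosomal acid lipase, did not pass. Of the 19 autophagy genes tested, 7 rose, 1 fell and 11 did not pass, 8 within the list (median log2 difference 0.17, 0.09 without A549 DMSO replicate 1, adjusted p = 0.00784, adjusted p = 0.18 with an estimated correlation). The cargo receptor SQSTM1 (654 ± 20.6 to 1795 ± 11.2) rose. So did WIPI1 (10.9 ± 2.18 to 36 ± 2.12) and GABARAPL1 (17.4 ± 5.13 to 49.6 ± 1.83), and ATG16L1 (30.4 ± 3.17 to 16.3 ± 1.64) fell.

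Sterol and fatty acid genes moved in part. Of the 20 cholesterol synthesis genes tested, 11 rose, 1 fell and 8 did not pass, 12 within the list (median log2 difference 0.25, adjusted p = 0.000354, adjusted p = 0.301 with an estimated correlation). FDPS (181 ± 6.7 to 269.6 ± 8.29), IDI1 (43.6 ± 3.56 to 64.2 ± 1.66), SC5D (11.6 ± 2.45 to 17.7 ± 1.89) and SQLE (52.4 ± 2.66 to 73.4 ± 3.9) rose (adjusted p at most 0.00457). HMGCS1 (64.1 ± 11.3 and 56.2 ± 2.99, adjusted p = 0.304) did not pass. Among sterol uptake genes SCARB1 (111 ± 9.98 to 159 ± 7.71) and the sterol sensor INSIG1 (31.9 ± 3.01 to 40.3 ± 2.21) rose, and TMEM97 (81.8 ± 7.63 to 57.9 ± 1.56) fell. Of the 10 LXR targets tested, 5 rose and 5 did not pass, 5 within the list (median log2 difference 0.52, adjusted p = 0.00604, adjusted p = 0.342 with an estimated correlation). They included APOE (6.85 ± 3.46 to 75 ± 10.3) and APOC1 (147 ± 43.9 to 347 ± 27.2), both apolipoproteins, the cholesterol exporter ABCA1 (2.14 ± 0.199 to 6.23 ± 0.554) and the receptor gene NR1H3 (13.7 ± 3.33 to 26.5 ± 0.613). ABCG1 (3.78 ± 0.63 and 3.34 ± 0.746, adjusted p = 0.606) and SREBF1 (213 ± 37.4 and 202 ± 7.37, adjusted p = 0.671) did not pass. Of the 12 fatty acid synthesis genes tested, 4 rose, 1 fell and 7 did not pass, 7 within the list (median log2 difference 0.26, adjusted p = 0.0458, adjusted p = 0.485 with an estimated correlation). SCD (303 ± 55.8 to 563 ± 26.1), ME1 (37.2 ± 2.85 to 64.9 ± 1.59) and FASN (119 ± 12.2 to 167 ± 6.52) rose, and ACLY (323 ± 11.6 to 247 ± 11.4) fell.

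Lipid storage and oxidation genes rose as lists. Of the 14 lipid droplet genes tested, 5 rose, 1 fell and 8 did not pass, 7 within the list (median log2 difference 0.12, 0.07 without A549 DMSO replicate 3 or 0.06 without LB DMSO replicate 2, adjusted p = 0.0287, adjusted p = 0.18 with an estimated correlation). The droplet coats PLIN2 (26.9 ± 1.71 to 43.3 ± 1.22) and PLIN4 (0.0867 ± 0.0153 to 2.64 ± 0.367) rose. BSCL2 (50.5 ± 6.63 to 78.7 ± 3.83) rose as well, and the lipase inhibitor G0S2 (3.09 ± 1.06 to 0.833 ± 0.235) fell. Of the 15 fatty acid oxidation genes tested, 6 rose, 2 fell and 7 did not pass, 8 within the list (median log2 difference 0.22, 0.13 without A549 DMSO replicate 1 or 0.14 without A549 DMSO replicate 3, adjusted p = 0.019, adjusted p = 0.459 with an estimated correlation). ANGPTL4 (8.88 ± 1.63 to 57.8 ± 3.45), CPT1A (30.6 ± 1.43 to 42.9 ± 1.64) and CPT2 (11.9 ± 0.269 to 14.6 ± 0.675) rose, and PDK4 (14.1 ± 4.34 to 5.39 ± 0.251) fell. The call of the fatty acid synthesis list was lost with a filter at a mean of 5 TPM (0.0658), after quantile normalization (0.0545), with array weights (0.0542), without A549 DMSO replicate 2 (0.105), without LB DMSO replicate 1 (0.0791), without LB DMSO replicate 3 (0.0631) and without LB amiodarone plus HPbCD replicate 3 (0.0511), over a range of 0.0102 to 0.485 among all alternatives. That of the lipid droplet list ended without A549 DMSO replicate 3 (0.0574) and without LB DMSO replicate 2 (0.0534), over a range of 2.28e-05 to 0.18 among all alternatives. The oxidation list lost its call without A549 DMSO replicate 2 (0.0798), over a range of 0.000692 to 0.459 among all alternatives.

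Epithelial junction and proliferation genes were lower in LB DMSO. Of the 14 epithelial junction genes tested, 2 rose, 10 fell and 2 did not pass, 12 within the list (median log2 difference -0.75, adjusted p = 0.000728, adjusted p = 0.0538 with an estimated correlation). The keratins KRT19 (233 ± 47.6 to 51.4 ± 7.04), KRT18 (3211 ± 88 to 1328 ± 66) and KRT8 (3994 ± 203 to 1674 ± 92.9) and the adhesion molecule EPCAM (9.46 ± 2.48 to 2.43 ± 0.36) fell, KRT18 and KRT8 having many pseudogene copies. Of the 25 proliferation genes tested, 20 fell and 5 did not pass, 21 within the list (median log2 difference -0.33, adjusted p = 2.2e-06, adjusted p = 0.342 with an estimated correlation). Examples were CCNB2 (108 ± 6.76 to 73.5 ± 4.53) and MCM2 (84.9 ± 5.91 to 58.6 ± 2.81), a cyclin and a replication helicase subunit, and AURKB (175 ± 23.1 to 121 ± 2.76) and TOP2A (211 ± 7.03 to 149 ± 11.4). Of the 4 metallothionein genes tested, 3 fell and 1 did not pass, 3 within the list (median log2 difference -0.92, adjusted p = 0.00592, adjusted p = 0.18 with an estimated correlation). They were MT1F (11.3 ± 1.56 to 0.967 ± 0.0569), MT1X (84 ± 5.58 to 31.8 ± 1.57) and MT2A (309 ± 47.8 to 220.3 ± 9.72), which share sequence with each other. Of the 26 ribosomal protein genes tested, 8 rose and 18 did not pass, 8 within the list (median log2 difference 0.07, adjusted p = 0.0168, adjusted p = 0.721 with an estimated correlation).

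Stress and interferon genes were higher. Of the 21 integrated stress response genes tested, 12 rose, 4 fell and 5 did not pass, 17 within the list (median log2 difference 0.33, adjusted p = 0.00304, adjusted p = 0.18 with an estimated correlation). TRIB3 (55.1 ± 0.463 to 98.9 ± 6.29) and DDIT3 (14.8 ± 1.58 to 23.8 ± 1.18), targets of ATF4, rose. So did CHAC1 (6.83 ± 1.07 to 15.1 ± 1.21) and NUPR1 (11.7 ± 3.44 to 22.3 ± 2.91), and VLDLR (10.1 ± 0.356 to 2.24 ± 0.489) fell. ATF3 (4.54 ± 1.49 and 6.1 ± 1.01, adjusted p = 0.143) did not pass. Of the 16 interferon-stimulated genes tested, 11 rose, 1 fell and 4 did not pass, 13 within the list (median log2 difference 0.79, adjusted p = 1.52e-05, adjusted p = 0.248 with an estimated correlation). IFI27 (0.913 ± 0.492 to 6.49 ± 1.41), OASL (0.527 ± 0.114 to 4.62 ± 0.693), IFI6 (5.55 ± 0.484 to 16.7 ± 1.83) and ISG15 (11.2 ± 2.08 to 27.7 ± 3.82) rose (adjusted p at most 0.000372).

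The lists not called in this comparison included genes that moved both ways. They were sterol uptake and SREBP2 regulation (3 rose and 2 fell of 9, 5 within the list, adjusted p = 0.57), phospholipid synthesis (1 rose and 4 fell of 18, 5 within the list, adjusted p = 0.596), sphingolipid synthesis (2 rose and 6 fell of 15, 9 within the list, adjusted p = 0.504) and endoplasmic reticulum chaperones (4 rose and 1 fell of 18, 4 within the list, adjusted p = 0.136). The stress lists were heat shock (1 rose and 3 fell of 12, 4 within the list, adjusted p = 0.688), NRF2 targets (8 rose and 7 fell of 19, 15 within the list, adjusted p = 0.596), xenobiotic metabolism (2 rose and 3 fell of 12, 6 within the list, adjusted p = 0.504) and p53 targets (4 rose and 2 fell of 18, 6 within the list, adjusted p = 0.293). The others were hypoxia and glycolysis (3 rose and 6 fell of 16, 9 within the list, adjusted p = 0.596), mitochondrially encoded genes (0 at an unadjusted limma p under 0.05 and 0 past the adjusted one of 13, 0 within the list, adjusted p = 0.736), mesenchymal transition and matrix (6 rose and 7 fell of 23, 15 within the list, adjusted p = 0.688), inflammatory mediators (4 rose and 6 fell of 14, 10 within the list, adjusted p = 0.968) and acute phase and coagulation (5 rose and 2 fell of 7, 7 within the list, adjusted p = 0.136). Median and mean differed in sign for NRF2 targets (median 0.08 and mean -0.14), and the camera direction of the mitochondrially encoded genes was up (median -0.01 and mean -0.004). The reductases AKR1B10 (2338 ± 319 to 631 ± 49.9), AKR1C3 (1496 ± 197 to 418 ± 34), AKR1C1 (376 ± 60.8 to 114 ± 13.7) and AKR1C2 (3203 ± 595 to 1051 ± 66.8) fell among NRF2 targets, the AKR1C levels being uncertain because the genes are nearly identical. CDKN1A (68.3 ± 12.3 to 182 ± 32.1) and GDF15 (79.2 ± 14.4 to 296 ± 15.2), a cell cycle inhibitor and a stress cytokine, rose among p53 targets. CDH2 (21.1 ± 3.95 to 0.907 ± 0.185) and FN1 (58.1 ± 3.91 to 16 ± 1.01), N-cadherin and fibronectin, fell where MMP2 (1.15 ± 0.191 to 11.6 ± 0.757) and SNAI1 (1.75 ± 0.495 to 9.02 ± 1.43) rose. PTGS2 (37.5 ± 10.7 to 142 ± 6.81) and ICAM1 (0.743 ± 0.669 to 4.38 ± 0.806) rose, and IL32 (13 ± 7.14 to 2.05 ± 0.501) and CXCL1 (23 ± 3.63 to 9.02 ± 1.46) fell, as did CXCL8 (2.62 ± 0.745 to 1.33 ± 0.0987). The call was lost for CXCL8 without A549 DMSO replicate 2 (adjusted p 0.00496 to 0.0596). CP (10.8 ± 4.69 to 48.7 ± 1.15), FGG (46 ± 23.1 to 121 ± 7.22) and FGA (35.1 ± 15.6 to 80.6 ± 5.35) rose among acute phase genes.

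Lists of other cell types had too few tested members for a test. Of the airway genes MUC5B (15.8 ± 3.11 to 6.07 ± 2.16) fell. All 3 fibroblast markers tested passed, LUM (0.27 ± 0.151 to 2.44 ± 0.506) and COL1A1 (4.13 ± 0.821 to 8.38 ± 0.241) rising and THY1 (9.19 ± 1.07 to 5.26 ± 1.34) falling. Of 3 leukocyte markers the lysosomal protein gene CD68 (11.2 ± 1.88 to 26.5 ± 1.39) rose and CD14 (4.76 ± 1.48 to 2.51 ± 0.407) fell, and of the endothelial list 1 gene was tested, ESAM (2.9 ± 0.64 to 1.03 ± 0.37), which fell. The test was lost for THY1 without LB DMSO replicate 3 (adjusted p 0.00759 to 0.0582) and CD14 without A549 DMSO replicate 1 or 3 or LB DMSO replicate 2 or 3 (adjusted p 0.00308 to 0.0925).

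In this comparison 4525 changed (1979 higher and 2546 lower) of the 13968 genes, 679 of them at least 2-fold (295 higher and 384 lower). The groups did not overlap in 6107 genes (43.7%, against 10% by chance). The balance turned with median-of-ratios scaling (2325 higher and 2167 lower) and quantile normalization (2373 and 2184), and the count of 2-fold changes was 301 with a pseudocount of 5 and 396 with a filter at a mean of 5 TPM. Of 28 lists tested 15 were called (11 up and 4 down), and with an estimated correlation 0 were (7 at an unadjusted p under 0.05), against 19 with fry, which does not set a list against other genes.

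**Figure D1:**
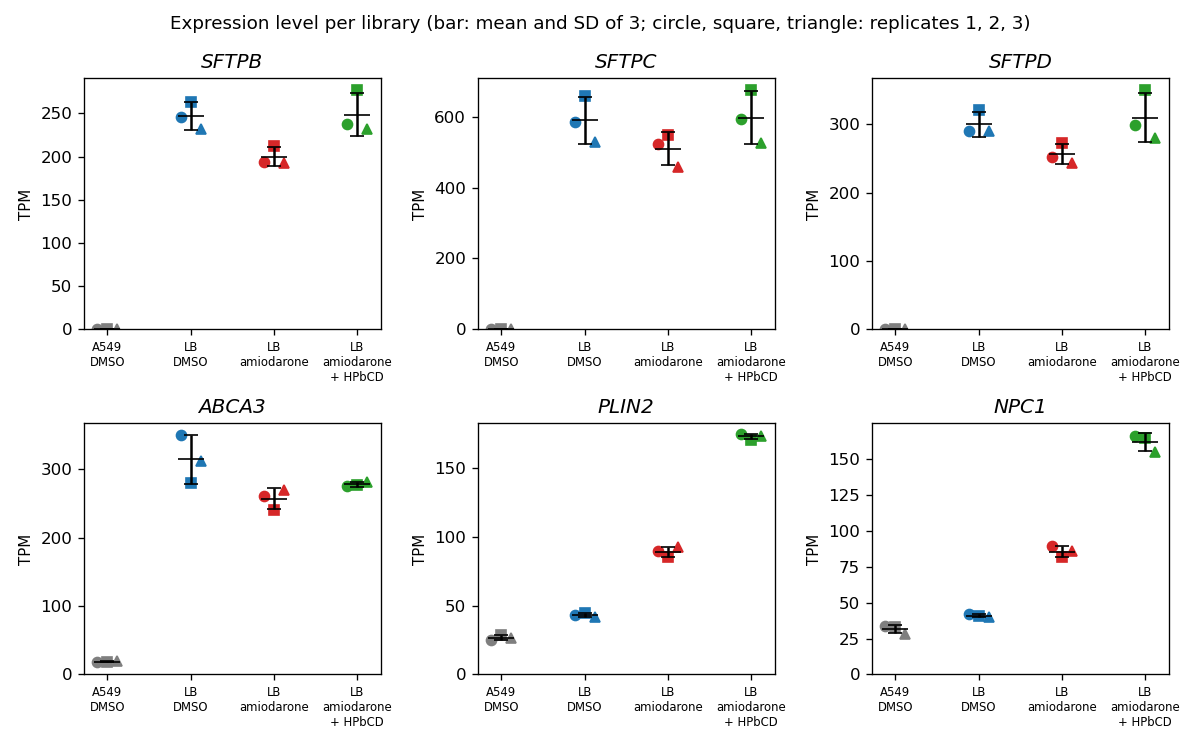
Expression in TPM (vertical axis, linear, from 0) of 6 genes in the 4 groups. Symbols are libraries (circle, square and triangle for replicates 1, 2 and 3) and bars the mean and SD of 3; PLIN2 and NPC1 were lowest in A549 and highest with HPbCD, where their means were 173 and 161 TPM.

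LB amiodarone was compared with LB DMSO to find what the drug changes in LB cells. Genes of cholesterol synthesis rose nearly as a block. HMGCS1 (chromosome 5, 43289395 to 43313512, minus strand), which makes HMG-CoA, rose from 56.2 ± 2.99 to 273 ± 40.6 TPM (log2 difference 2.25 ± 0.12 SE, adjusted p = 1.68e-07). FDPS (chromosome 1, 155308748 to 155320666, plus strand), farnesyl diphosphate synthase, reached the highest level of the pathway, 269.6 ± 8.29 to 1348 ± 65.6 TPM. Of the 20 cholesterol synthesis genes tested, 19 rose and 1 did not pass, 20 within the list (median log2 difference 1.63, adjusted p = 8.05e-48, adjusted p = 0.00212 with an estimated correlation). MSMO1 (26.3 ± 0.0987 to 142 ± 15.9), MVD (47.9 ± 1.24 to 238 ± 17.3) and ACAT2 (55.7 ± 2.43 to 239 ± 26.5) rose. So did IDI1 (64.2 ± 1.66 to 246 ± 33.9), LSS (25 ± 1.9 to 90.3 ± 4.99) and SQLE (73.4 ± 3.9 to 221 ± 21) (adjusted p at most 1.71e-07). FDPS has pseudogenes that can take its reads.

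Uptake and fatty acid genes rose with them. Of the 9 sterol uptake genes tested, 8 rose and 1 did not pass, 8 within the list (median log2 difference 1.04, adjusted p = 1.5e-15, adjusted p = 0.00191 with an estimated correlation). INSIG1 (chromosome 7, 155297776 to 155310235, plus strand) rose from 40.3 ± 2.21 to 174 ± 13.6 TPM (log2 difference 2.08 ± 0.087 SE, adjusted p = 1.69e-08). STARD4 (12.9 ± 0.669 to 41.9 ± 3.68), a sterol carrier, and LPIN1 (16.3 ± 2.38 to 45 ± 7.13) rose too. Of the 12 fatty acid synthesis genes tested, 12 rose, 12 within the list (median log2 difference 0.92, adjusted p = 2.53e-20, adjusted p = 0.00661 with an estimated correlation). The largest were ACSS2 (20.9 ± 1.51 to 116 ± 19.2), an acetyl-CoA synthetase, and the desaturases SCD (563 ± 26.1 to 1694 ± 33), FADS1 (211 ± 8.62 to 559 ± 9.08) and FADS2 (442 ± 15.8 to 1129 ± 21.1). Of the 18 phospholipid synthesis genes tested, 4 rose and 14 did not pass, 4 within the list (median log2 difference 0.15, adjusted p = 0.000876, adjusted p = 0.0175 with an estimated correlation). PCYT2 (28.6 ± 0.18 to 71.3 ± 6.4) and CHKA (21.5 ± 0.512 to 36.6 ± 2.19), of the ethanolamine and choline branches, were among them. Of the 15 sphingolipid genes tested, 1 rose and 14 did not pass, 3 within the list (median log2 difference 0.13, adjusted p = 0.0178, adjusted p = 0.344 with an estimated correlation). The gene past the test was CERS4 (2.33 ± 0.299 to 4.15 ± 0.341). The call was lost for CERS4 without LB DMSO replicate 1 (adjusted p 0.0088 to 0.0518). The list call was lost without LB DMSO replicate 2 (0.0607), over a range of 0.00203 to 0.344 among all alternatives.

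LXR targets, which include sterol exporters, were not called as a list (1 rose and 1 fell of 10, 4 within the list, adjusted p = 0.685). ABCG1 (3.34 ± 0.746 to 1.09 ± 0.303) fell. ABCA1 (6.23 ± 0.554 and 4.15 ± 0.791, adjusted p = 0.0695) and SREBF1 (202 ± 7.37 and 207 ± 12.1, adjusted p = 0.862) did not pass. The largest single rise of the comparison was in ALDOC (chromosome 17, 28573115 to 28577264, minus strand), a glycolytic aldolase, from 5.41 ± 0.597 to 95.1 ± 5.97 TPM (log2 difference 3.91 ± 0.10 SE, adjusted p = 3.73e-10). Of the 16 hypoxia and glycolysis genes tested, 9 rose, 1 fell and 6 did not pass, 12 within the list (median log2 difference 0.40, adjusted p = 1.44e-07, adjusted p = 0.0175 with an estimated correlation). P4HA1 (26.2 ± 1.21 to 42.6 ± 5.09), NDRG1 (9.09 ± 0.421 to 14.7 ± 1.56) and BNIP3 (44.3 ± 2.11 to 66.7 ± 4.8) were examples.

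Lysosomal genes rose further. Of the 33 lysosomal genes tested, 24 rose and 9 did not pass, 26 within the list (median log2 difference 0.34, adjusted p = 1.42e-20, adjusted p = 0.0175 with an estimated correlation). NEU1 (64.8 ± 2.23 to 214 ± 3.06) and GPNMB (3.24 ± 0.52 to 12.3 ± 1.53) rose most, and the cholesterol exporters NPC1 (chromosome 18, 23506184 to 23586898, minus strand) and NPC2 rose from 40.9 ± 1.11 to 85.5 ± 3.86 TPM (log2 difference 1.04 ± 0.068 SE, adjusted p = 1.01e-06) and from 214 ± 12.3 to 414 ± 12.9 TPM. LIPA (61.5 ± 2.87 to 111 ± 6.06) rose. LAMP1 (74.1 ± 0.809 and 81.9 ± 0.802, adjusted p = 0.0597) did not pass. Of the 19 autophagy genes tested, 5 rose and 14 did not pass, 5 within the list (median log2 difference 0.11, 0.05 without LB amiodarone replicate 2, adjusted p = 0.00186, adjusted p = 0.106 with an estimated correlation). SQSTM1 (1795 ± 11.2 to 2769 ± 61.4), OPTN (34.2 ± 3.33 to 55.5 ± 1.97) and WIPI1 (36 ± 2.12 to 57.4 ± 2.35) rose. MAP1LC3B (35 ± 1.81 to 44.9 ± 2.53) rose as well. PLIN2 (chromosome 9, 19108375 to 19149290, minus strand), a lipid droplet coat, rose from 43.3 ± 1.22 to 89.3 ± 3.54 TPM (log2 difference 1.03 ± 0.054 SE, adjusted p = 1.34e-07), the 1 member of its list to pass, which was not called (adjusted p = 0.781).

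Stress genes of the ATF4 branch rose. Of the 21 integrated stress response genes tested, 14 rose and 7 did not pass, 15 within the list (median log2 difference 0.39, adjusted p = 3.15e-12, adjusted p = 0.00852 with an estimated correlation). NUPR1 (22.3 ± 2.91 to 72.6 ± 5.69) and TRIB3 (98.9 ± 6.29 to 259 ± 3.65) rose. DDIT3 (23.8 ± 1.18 to 49.1 ± 0.352) and CHAC1 (15.1 ± 1.21 to 29.1 ± 2.41) rose as well, and so did ATF3 (6.1 ± 1.01 to 10.4 ± 2.39). The test was lost for ATF3 without A549 DMSO replicate 3 or LB DMSO replicate 1, 2 or 3 or LB amiodarone replicate 1 or 2 or LB amiodarone plus HPbCD replicate 1, 2 or 3 (adjusted p 0.0165 to 0.159). Of the 25 proliferation genes tested, 16 fell and 9 did not pass, 22 within the list (median log2 difference -0.30, adjusted p = 5.37e-15, adjusted p = 0.11 with an estimated correlation). The kinases PLK1 (101 ± 5.86 to 68.9 ± 6.18) and AURKB (121 ± 2.76 to 91.5 ± 2.04), MCM5 (124 ± 6.5 to 87.7 ± 6.2) and UBE2C (215 ± 9.41 to 161 ± 7.83) were the largest. Of the 16 interferon-stimulated genes tested, 6 rose and 10 did not pass, 6 within the list (median log2 difference 0.24, 0.09 without LB amiodarone replicate 1 or 0.36 without LB amiodarone replicate 3, adjusted p = 2.98e-05, adjusted p = 0.279 with an estimated correlation). IFIT2 (2.93 ± 0.381 to 9.76 ± 1.71), IFIT3 (4.04 ± 0.421 to 12 ± 0.96), IFIT1 (4.96 ± 0.632 to 14 ± 1.72) and OASL (4.62 ± 0.693 to 10.3 ± 1.49) rose (adjusted p at most 0.000281). The replicates were uneven: the list's median log2 level above the LB DMSO mean was 0.685, 0.24 and 0.055 in amiodarone replicates 1, 2 and 3, and 0.08, 0.076 and -0.116 in LB DMSO.

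Within the naming rule the largest log2 falls were HTRA3 (11.8 ± 1.41 to 4.4 ± 0.491), a secreted serine protease, MYCBP (21.5 ± 1.35 to 9.4 ± 4.77), the imprinted noncoding RNA H19 (31.5 ± 5.47 to 13.2 ± 2.41) and CRABP2 (7.34 ± 0.659 to 3.33 ± 0.883), a retinoic acid carrier. RRAD (13.4 ± 2.2 to 7 ± 1.46) and NPTX1 (18.3 ± 1.99 to 10.3 ± 1.11) were next. The 10 largest also held CORO7 (12.5 ± 1.7 to 7.17 ± 0.886), LFNG (6 ± 0.445 to 3.3 ± 0.191), TAP2 (38.4 ± 6.41 to 24.3 ± 2.83) and CRIP2 (116 ± 3.64 to 76.1 ± 5.94). Calls were lost for MYCBP without LB DMSO replicate 1 (adjusted p 0.00132 to 0.053), CORO7 without LB DMSO replicate 2 (adjusted p 0.00554 to 0.0525) and TAP2 without LB DMSO replicate 2 or 3 or LB amiodarone replicate 1 or 3 (adjusted p 0.018 to 0.114). Surfactant genes were slightly lower or not past the test. SFTPB (247 ± 15.9 to 199.8 ± 10.9) and ABCA3 (314 ± 35.3 to 257 ± 15.3) fell, with adjusted p = 0.0237 and 0.0321. SFTPC (589.9 ± 66.3 and 509 ± 45.8, adjusted p = 0.394), SFTPD (300.0 ± 18.2 and 256 ± 14.8, adjusted p = 0.156) and NAPSA (2.96 ± 0.91 and 1.76 ± 0.197, adjusted p = 0.192) did not pass. Nor did CAV1 (139 ± 14.7 and 107 ± 13, adjusted p = 0.0811), CDKN1A (182 ± 32.1 and 198 ± 37, adjusted p = 0.757) and CXCL8 (1.33 ± 0.0987 and 1.6 ± 0.374, adjusted p = 0.654). The 2 falls were lost for SFTPB without LB DMSO replicate 1 or 2 or LB amiodarone replicate 1 or 3 (adjusted p 0.0118 to 0.093) and ABCA3 without LB DMSO replicate 1 or 3 or LB amiodarone replicate 1 or 2 (adjusted p 0.00925 to 0.114).

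The other 17 lists tested were not called (adjusted p = 0.0889 to 0.947). Median and mean differed in sign for LXR targets (median 0.01 and mean -0.05), lipid droplets (median -0.02 and mean 0.05), xenobiotic metabolism (median -0.09 and mean 0.02), p53 targets (median -0.01 and mean 0.04) and epithelial junctions (median -0.11 and mean 0.03).

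Amiodarone changed 1204 genes (684 higher and 520 lower), 85 of them at least 2-fold (78 higher and 7 lower), and 49 at least 2-fold with a pseudocount of 5. The count fell to 691, 750 and 628 without LB DMSO replicates 1, 2 and 3, and to 685 and 718 without LB amiodarone replicates 2 and 3. The groups did not overlap in 4186 genes (30.0%, against 10% by chance). Of 28 lists 11 were called (10 up and 1 down), 7 with an estimated correlation and 13 with fry.

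**Figure D2:**
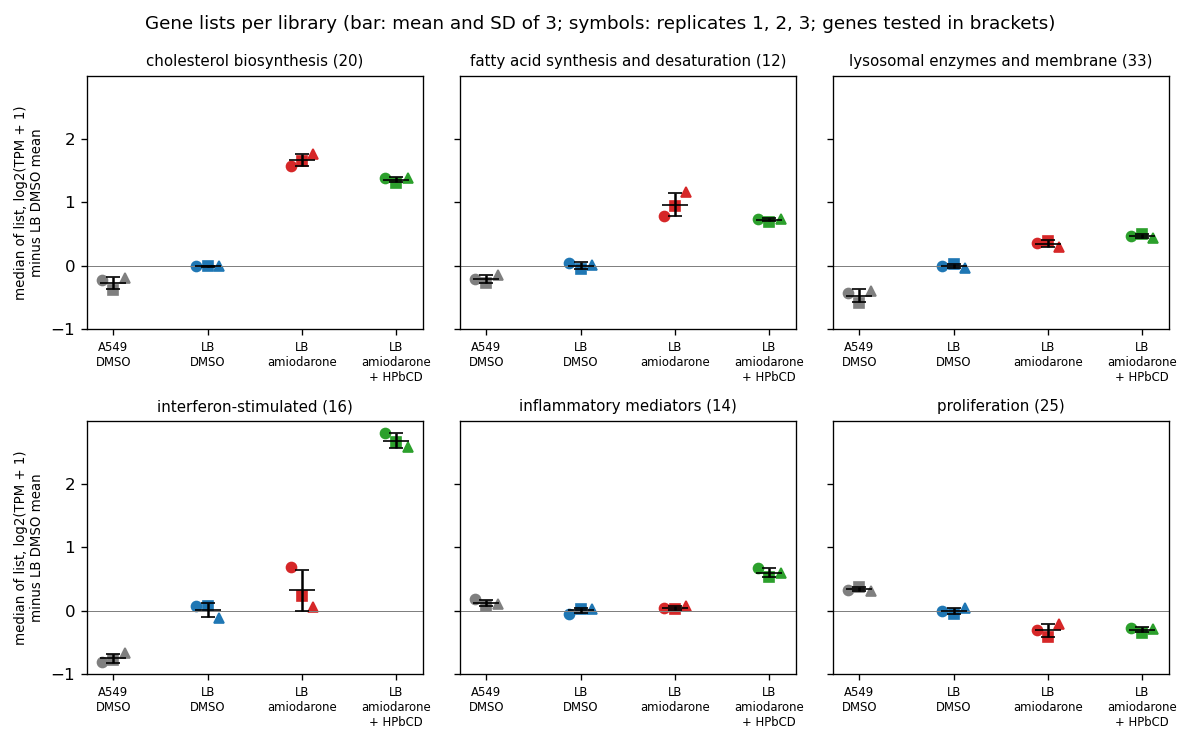
Median of the log2(TPM + 1) values of 6 gene lists in each library, after subtracting each gene's mean in LB DMSO (vertical axis, log2), by group. Symbols are libraries (circle, square and triangle for replicates 1, 2 and 3), bars the mean and SD of 3, and tested genes stand in brackets; the cholesterol list is highest with amiodarone (median log2 difference 1.63 from LB DMSO) and the interferon list with HPbCD (2.76).

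LB amiodarone plus HPbCD was compared with LB amiodarone to find what HPbCD before the drug changes. Interferon-stimulated genes rose. ISG15 (chromosome 1, 1001138 to 1014540, plus strand), a ubiquitin-like modifier, rose from 49.9 ± 14.2 to 292 ± 29.7 TPM (log2 difference 2.56 ± 0.19 SE, adjusted p = 1.25e-05), MX1 (chromosome 21, 41420304 to 41459214, plus strand), an antiviral GTPase, from 3.15 ± 0.985 to 28.7 ± 6.54 TPM (log2 difference 2.84 ± 0.18 SE, adjusted p = 6.33e-06), and IFI27 (chromosome 14, 94104836 to 94116698, plus strand) from 6.91 ± 2.7 to 63.1 ± 21.6 TPM (log2 difference 3.02 ± 0.28 SE, adjusted p = 7.19e-05). Of the 16 interferon-stimulated genes tested, 16 rose, 16 within the list (median log2 difference 1.88, adjusted p = 2.06e-38, adjusted p = 0.00763 with an estimated correlation). IFI6 (22.2 ± 8.22 to 127 ± 35.1), IFIT1 (14 ± 1.72 to 66.2 ± 11.5), OAS1 (15.1 ± 2.08 to 58.8 ± 7.79) and OASL (10.3 ± 1.49 to 40.3 ± 2.65) rose too, as did IRF7 (5.41 ± 1.28 to 29 ± 2.14), a transcription factor of the interferon response, the chemokine CCL5 (11.2 ± 1.88 to 51.5 ± 8.35) and IFITM1 (1.58 ± 0.371 to 8.85 ± 2.8) (adjusted p at most 0.00233). IFITM1 shares sequence with its neighbours.

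Inflammatory mediators rose as a list. Of the 14 inflammatory mediator genes tested, 6 rose and 8 did not pass, 11 within the list (median log2 difference 0.60, adjusted p = 1.37e-10, adjusted p = 0.00314 with an estimated correlation). The cytokines IL6 (1.15 ± 0.0907 to 6.64 ± 2.06) and IL11 (6.61 ± 0.968 to 13.3 ± 0.488) and PTGS2 (232 ± 17 to 407 ± 11.5), the inducible cyclooxygenase, rose. CXCL8 (1.6 ± 0.374 and 3.07 ± 0.382, adjusted p = 0.0527) did not pass.

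Part of the sterol pathway fell. Of the 20 cholesterol synthesis genes tested, 8 fell and 12 did not pass, 13 within the list (median log2 difference -0.28, adjusted p = 1.29e-10, adjusted p = 0.0961 with an estimated correlation). ACAT2 (239 ± 26.5 to 159.7 ± 7.05) and LSS (90.3 ± 4.99 to 62.9 ± 3.16) fell. FDPS (1348 ± 65.6 to 943 ± 16.7) and FDFT1 (661 ± 51 to 464 ± 7.5) fell as well. HMGCS1 (273 ± 40.6 and 255 ± 16.5, adjusted p = 0.767) and SQLE (221 ± 21 and 187 ± 14.5, adjusted p = 0.121) did not pass. The sterol sensor gene INSIG1 (174 ± 13.6 and 195 ± 18.9, adjusted p = 0.348) was not past the test. Of the 12 fatty acid synthesis genes tested, 6 fell and 6 did not pass, 7 within the list (median log2 difference -0.31, adjusted p = 5.25e-07, adjusted p = 0.0961 with an estimated correlation). ACLY (476 ± 13.2 to 346 ± 16.8) and ME1 (97.8 ± 6.43 to 72.8 ± 4.72) fell. SCD (1694 ± 33 to 1261 ± 75.8) fell too. The call was lost for SCD without LB DMSO replicate 1, 2 or 3 or LB amiodarone replicate 1, 2 or 3 or LB amiodarone plus HPbCD replicate 1, 2 or 3 (adjusted p 0.000447 to 0.147). Of the 15 fatty acid oxidation genes tested, 1 fell and 14 did not pass, 7 within the list (median log2 difference -0.09, -0.15 without LB amiodarone plus HPbCD replicate 1, adjusted p = 0.017, adjusted p = 0.418 with an estimated correlation). Among LXR targets, not called (1 rose of 10, 2 within the list, adjusted p = 0.489), ABCA1 (4.15 ± 0.791 to 7.04 ± 1.52) rose with adjusted p = 0.0404. ABCG1 (1.09 ± 0.303 and 1.38 ± 0.476, adjusted p = 0.7) and SREBF1 (207 ± 12.1 and 181 ± 7.5, adjusted p = 0.341) did not pass. The rise was lost for ABCA1 without A549 DMSO replicate 1 or LB DMSO replicate 1, 2 or 3 or LB amiodarone replicate 1, 2 or 3 or LB amiodarone plus HPbCD replicate 1 or 2 (adjusted p 0.0154 to 0.163).

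Some lysosomal genes rose again. Of the 33 lysosomal genes tested, 10 rose and 23 did not pass, 15 within the list (median log2 difference 0.13, adjusted p = 2.4e-08, adjusted p = 0.17 with an estimated correlation). NPC1 rose from 85.5 ± 3.86 to 161 ± 6.16 TPM (log2 difference 0.91 ± 0.068 SE, adjusted p = 1.37e-05), and CTSL (1154 ± 53.8 to 1824 ± 52.8) and CTSB (403 ± 19 to 579.6 ± 43.5) rose. GPNMB (12.3 ± 1.53 to 22.4 ± 2.23) rose as well. LIPA (111 ± 6.06 and 97.4 ± 2.27, adjusted p = 0.149) and LAMP1 (81.9 ± 0.802 and 83.8 ± 3, adjusted p = 0.759) did not pass. The call was lost for GPNMB without LB amiodarone replicate 3 or LB amiodarone plus HPbCD replicate 1 or 2 (adjusted p 0.00275 to 0.0639). PLIN2 rose from 89.3 ± 3.54 to 173 ± 2 TPM (log2 difference 0.95 ± 0.054 SE, adjusted p = 6.33e-06), though the lipid droplet list was not called (2 rose of 14, 4 within the list, adjusted p = 0.176). CD68 (35.8 ± 2.96 to 83.3 ± 2.23) rose among the 3 leukocyte markers tested. Of the 19 autophagy genes tested, 2 rose, 1 fell and 16 did not pass, 4 within the list (median log2 difference 0.10, adjusted p = 0.0081, adjusted p = 0.17 with an estimated correlation). SQSTM1 (2769 ± 61.4 to 3754 ± 60.8) rose.

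Several stress lists rose. Of the 12 heat shock genes tested, 3 rose and 9 did not pass, 10 within the list (median log2 difference 0.23, adjusted p = 3.02e-05, adjusted p = 0.244 with an estimated correlation). BAG3 (89.3 ± 3.26 to 116 ± 2.64) rose. Of the 18 endoplasmic reticulum chaperone genes tested, 2 rose and 16 did not pass, 7 within the list (median log2 difference 0.12, adjusted p = 0.000334, adjusted p = 0.325 with an estimated correlation). SDF2L1 (60.1 ± 1.53 to 80.3 ± 4.42) was an example. Of the 16 hypoxia and glycolysis genes tested, 5 rose and 11 did not pass, 8 within the list (median log2 difference 0.24, adjusted p = 5.25e-05, adjusted p = 0.0961 with an estimated correlation). NDRG1 (14.7 ± 1.56 to 40.8 ± 3.79) and BNIP3 (66.7 ± 4.8 to 94.9 ± 7.85) rose. Of the 18 p53 target genes tested, 5 rose and 13 did not pass, 6 within the list (median log2 difference 0.14, 0.08 without LB amiodarone replicate 3 or 0.05 without LB amiodarone plus HPbCD replicate 2, adjusted p = 0.0254, adjusted p = 0.636 with an estimated correlation). The p53 call was lost after quantile normalization (0.0554), without LB amiodarone replicate 1 (0.0563), without LB amiodarone replicate 3 (0.148), without LB amiodarone plus HPbCD replicate 2 (0.267) and with fry (0.225), over a range of 0.00252 to 0.636 among all alternatives. In the integrated stress response list, which was not called (3 rose, 4 fell and 14 did not pass of 21, 10 within the list, adjusted p = 0.761), PPP1R15A (32.8 ± 3.73 to 65.1 ± 1.73), CEBPB (76.7 ± 6.45 to 121 ± 9.81) and DDIT3 (49.1 ± 0.352 to 67.1 ± 1.09) rose and the serine synthesis enzymes PHGDH (104 ± 9.48 to 64.8 ± 7.05) and PSPH (60.7 ± 3.53 to 38.9 ± 2.23) fell. ATF3 (10.4 ± 2.39 and 16.2 ± 0.878, adjusted p = 0.0952), TRIB3 (259 ± 3.65 and 282 ± 4.69, adjusted p = 0.179) and CDKN1A (198 ± 37 and 231 ± 40.8, adjusted p = 0.561) did not pass.

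Surfactant genes differed little. Of the 9 alveolar type II genes tested, 1 rose and 8 did not pass, 1 within the list (median log2 difference 0.18, adjusted p = 0.0254, adjusted p = 0.17 with an estimated correlation). SFTPB (199.8 ± 10.9 to 249 ± 24.5) rose with adjusted p = 0.0336. SFTPC (509 ± 45.8 and 597 ± 74.7, adjusted p = 0.424), SFTPD (256 ± 14.8 and 309 ± 35.9, adjusted p = 0.144) and ABCA3 (257 ± 15.3 and 278 ± 3.3, adjusted p = 0.455) did not pass. Nor did NAPSA (1.76 ± 0.197 and 1.94 ± 0.573, adjusted p = 0.9) and CAV1 (107 ± 13 and 106 ± 12.3, adjusted p = 0.947). The rise was lost for SFTPB without LB DMSO replicate 1 or LB amiodarone replicate 1 or 3 or LB amiodarone plus HPbCD replicate 1 or 2 (adjusted p 0.0304 to 0.121). The call of the list was lost with a pseudocount of 0.1 (0.0672), with no filter on low values (0.201), after quantile normalization (0.0727), without LB amiodarone replicate 3 (0.149) and without LB amiodarone plus HPbCD replicate 2 (0.0829), over a range of 0.0102 to 0.201 among all alternatives. Ribosomal protein genes were called down as a list. Of the 26 ribosomal protein genes tested, 0 passed the limma test (3 at an unadjusted p under 0.05), 0 within the list (median log2 difference -0.05, -0.02 without LB amiodarone replicate 1 or -0.07 without LB amiodarone replicate 2, adjusted p = 0.0254, adjusted p = 0.674 with an estimated correlation). That call was lost after median-of-ratios scaling (0.0585), after quantile normalization (0.348), without LB amiodarone replicate 1 (0.426), without LB amiodarone plus HPbCD replicate 2 (0.167) and with fry (0.215), over a range of 0.000533 to 0.674 among all alternatives.

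Among the largest falls were TPPP3 (14.4 ± 0.96 to 7.13 ± 1.18) and NOTCH3 (7.11 ± 1.24 to 3.65 ± 0.136), a tubulin-binding protein and a Notch receptor, CBS (31.2 ± 1.62 to 18.1 ± 2.72) and GSTM2 (6.33 ± 0.616 to 3.44 ± 0.696), cystathionine synthase and a glutathione transferase, and the antisense RNA GACAT2 (30.9 ± 6.28 to 16.2 ± 2.87). MTCP1 (6.47 ± 1.05 to 2.55 ± 0.995), COL1A1 (7.49 ± 1.52 to 3.57 ± 0.884) and COL26A1 (21.5 ± 1.17 to 11.7 ± 1.5) fell as well. Calls were lost for MTCP1 without LB DMSO replicate 2 or LB amiodarone replicate 1, 2 or 3 or LB amiodarone plus HPbCD replicate 1 or 2 (adjusted p 0.0233 to 0.145), COL1A1 without LB amiodarone replicate 3 (adjusted p 0.00681 to 0.0509) and COL26A1 without LB amiodarone replicate 1 or LB amiodarone plus HPbCD replicate 1 or 3 (adjusted p 0.00135 to 0.0651). MMP2 (9.05 ± 0.791 to 5.1 ± 0.334) and COL5A1 (9.42 ± 0.311 to 5.57 ± 0.243), a matrix protease and a collagen, and CYP24A1 (349.5 ± 18.3 to 225 ± 16.4), the vitamin D hydroxylase, fell, and MT2A (251 ± 10.4 to 364 ± 8.57) rose. The other 15 lists tested were not called (adjusted p = 0.0977 to 0.788). Median and mean differed in sign for sphingolipid synthesis (median -0.002 and mean 0.05) and metallothioneins (median -0.01 and mean 0.10).

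With HPbCD 568 genes changed (378 higher and 190 lower), 50 at least 2-fold (47 higher and 3 lower), and 23 with a pseudocount of 5 and 30 with a filter at a mean of 5 TPM. The count of changed genes was 345, 330 and 302 without LB amiodarone replicates 1, 2 and 3, and 280, 340 and 300 without LB amiodarone plus HPbCD replicates 1, 2 and 3. The groups did not overlap in 3509 genes (25.1%, against 10% by chance). Of 28 lists 13 were called (9 up and 4 down), 2 with an estimated correlation and 13 with fry.

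Whether HPbCD moved the amiodarone-changed genes back was asked over the genes called in both comparisons. Of these, 71 moved in opposite directions and 112 in the same. Genes that rose with amiodarone and fell with HPbCD numbered 46, against 9.30 for independent lists, and included the cholesterol genes FDPS, ACAT2 and LSS. Those that fell and then rose numbered 25, against 14.1. Genes that rose in both numbered 99, against 18.5, and included NPC1, PLIN2, SQSTM1 and IFIT1, and 13 fell in both, against 7.07. By list, all 8 cholesterol synthesis genes and all 6 fatty acid synthesis genes called in both went opposite ways, as did 4 of 6 integrated stress response genes. All 9 lysosomal, 6 interferon-stimulated and 4 hypoxia genes called in both went the same way. Both comparisons share the LB amiodarone libraries. The 100 simulated draws had no effect to call, so their 0 genes called in both decide nothing. The 3 shared libraries were too few to divide, so how many opposite calls come from the shared group is not known. Across genes the fold changes correlated at -0.165, against -0.495 (-0.55 to -0.426) in the simulated draws, and the covariance was -0.0117 against -0.019 (-0.0227 to -0.0152), a difference of 0.0073. The negative relation is thus no sign by itself of a move back.

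The count of opposite calls moved with the libraries. It was 113 without A549 DMSO replicate 2, 45, 43 and 45 without LB DMSO replicates 1, 2 and 3, and 33 and 31 without LB amiodarone replicates 2 and 3. Without LB amiodarone plus HPbCD replicates 1, 2 and 3 it was 33, 39 and 37. The correlation was -0.27, -0.268 and -0.249 without LB amiodarone replicates 1, 2 and 3, and -0.257 with a pseudocount of 0.1. The covariance was -0.02184, -0.02163 and -0.01954 without these libraries, -0.0363 and -0.003335 with pseudocounts of 0.1 and 5, -0.004883 with a filter at a mean of 5 TPM and -0.003899 with protein-coding genes only. The simulation was not repeated under these settings, so what shared libraries alone would give there is not known.

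**Figure D3:**
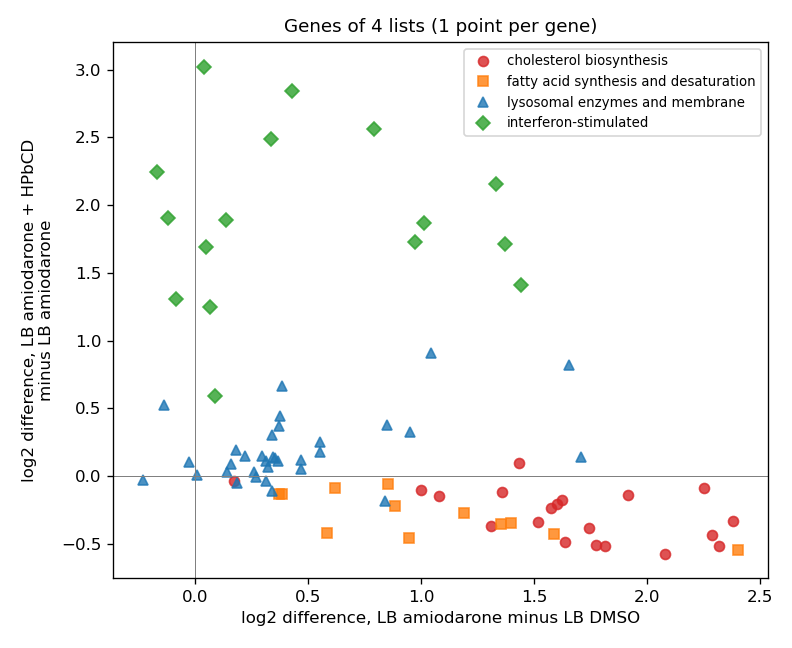
Log2 difference of the genes of 4 lists between LB amiodarone and LB DMSO (horizontal axis) and between LB amiodarone plus HPbCD and LB amiodarone (vertical axis), with 1 point per gene and a colour and shape per list. Cholesterol synthesis genes lie to the right with medians of 1.63 and -0.28, and interferon-stimulated genes lie high, with a vertical median of 1.88.

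LB amiodarone plus HPbCD was compared with LB DMSO to find how far the cells given both compounds were from vehicle. Interferon-stimulated, sterol and lysosomal genes were all higher. Of the 16 interferon-stimulated genes tested, 16 rose, 16 within the list (median log2 difference 2.76, adjusted p = 1.51e-25, adjusted p = 0.0107 with an estimated correlation). IFIT1 (4.96 ± 0.632 to 66.2 ± 11.5), ISG15 (27.7 ± 3.82 to 292 ± 29.7), MX1 (2.03 ± 0.197 to 28.7 ± 6.54) and IFIT3 (4.04 ± 0.421 to 41.8 ± 3.98) rose (adjusted p at most 1.64e-07). Of the 14 inflammatory mediator genes tested, 9 rose and 5 did not pass, 11 within the list (median log2 difference 0.60, adjusted p = 8.89e-08, adjusted p = 0.00581 with an estimated correlation). IL6 (1.12 ± 0.42 to 6.64 ± 2.06) and PTGS2 (142 ± 6.81 to 407 ± 11.5) rose. CXCL8 (1.33 ± 0.0987 to 3.07 ± 0.382) rose as well.

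Sterol genes stayed above vehicle. Of the 20 cholesterol synthesis genes tested, 19 rose and 1 did not pass, 20 within the list (median log2 difference 1.35, adjusted p = 5.18e-31, adjusted p = 0.00613 with an estimated correlation). HMGCS1 (56.2 ± 2.99 to 255 ± 16.5), MSMO1 (26.3 ± 0.0987 to 112 ± 9.18), FDPS (269.6 ± 8.29 to 943 ± 16.7) and SQLE (73.4 ± 3.9 to 187 ± 14.5) rose. Of the 9 sterol uptake genes tested, 8 rose and 1 did not pass, 8 within the list (median log2 difference 1.12, adjusted p = 2.38e-10, adjusted p = 0.00581 with an estimated correlation). INSIG1 (40.3 ± 2.21 to 195 ± 18.9) rose. Of the 12 fatty acid synthesis genes tested, 11 rose and 1 did not pass, 12 within the list (median log2 difference 0.73, adjusted p = 7.02e-11, adjusted p = 0.0178 with an estimated correlation). Of the 18 phospholipid synthesis genes tested, 7 rose and 11 did not pass, 8 within the list (median log2 difference 0.17, 0.11 without LB DMSO replicate 1, adjusted p = 0.000113, adjusted p = 0.0107 with an estimated correlation). Of the 15 sphingolipid genes tested, 4 rose, 1 fell and 10 did not pass, 5 within the list (median log2 difference 0.08, adjusted p = 0.0426, adjusted p = 0.479 with an estimated correlation). The sphingolipid call was lost after quantile normalization (0.0612), with only the 2 groups compared in the fit (0.0566), with protein-coding genes only (0.0588), without LB DMSO replicate 2 (0.088) and without LB amiodarone plus HPbCD replicate 1 (0.053), over a range of 0.00591 to 0.479 among all alternatives. ALDOC (5.41 ± 0.597 to 74.9 ± 2.91) rose most of all genes, APOC1 (347 ± 27.2 to 695 ± 30.9) rose and ABCG1 (3.34 ± 0.746 to 1.38 ± 0.476) fell. ABCA1 (6.23 ± 0.554 and 7.04 ± 1.52, adjusted p = 0.594) and SREBF1 (202 ± 7.37 and 181 ± 7.5, adjusted p = 0.326) did not pass.

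Of the 33 lysosomal genes tested, 28 rose and 5 did not pass, 29 within the list (median log2 difference 0.48, adjusted p = 1.41e-22, adjusted p = 0.0129 with an estimated correlation). GPNMB rose from 3.24 ± 0.52 to 22.4 ± 2.23 TPM (log2 difference 2.47 ± 0.16 SE, adjusted p = 6.07e-07) and NPC1 from 40.9 ± 1.11 to 161 ± 6.16 TPM (log2 difference 1.95 ± 0.068 SE, adjusted p = 2.4e-09). LIPA (61.5 ± 2.87 to 97.4 ± 2.27) rose, as did LAMP1 (74.1 ± 0.809 to 83.8 ± 3). The call was lost for LAMP1 without LB DMSO replicate 3 or LB amiodarone plus HPbCD replicate 2 (adjusted p 0.012 to 0.0578). PLIN2 rose from 43.3 ± 1.22 to 173 ± 2 TPM (log2 difference 1.98 ± 0.054 SE, adjusted p = 3.51e-10). Of the 19 autophagy genes tested, 6 rose, 1 fell and 12 did not pass, 7 within the list (median log2 difference 0.20, adjusted p = 2.58e-05, adjusted p = 0.0281 with an estimated correlation). SQSTM1 (1795 ± 11.2 to 3754 ± 60.8) rose. Of the 21 integrated stress response genes tested, 11 rose, 2 fell and 8 did not pass, 14 within the list (median log2 difference 0.31, adjusted p = 2.2e-05, adjusted p = 0.0441 with an estimated correlation). TRIB3 (98.9 ± 6.29 to 282 ± 4.69) and DDIT3 (23.8 ± 1.18 to 67.1 ± 1.09) rose. PPP1R15A (21.8 ± 1.37 to 65.1 ± 1.73), NUPR1 (22.3 ± 2.91 to 59.9 ± 3.72) and ATF3 (6.1 ± 1.01 to 16.2 ± 0.878) rose as well. Of the 18 endoplasmic reticulum chaperone genes tested, 10 rose and 8 did not pass, 12 within the list (median log2 difference 0.21, adjusted p = 5.17e-05, adjusted p = 0.258 with an estimated correlation). Of the 12 heat shock genes tested, 4 rose and 8 did not pass, 6 within the list (median log2 difference 0.19, adjusted p = 0.0162, adjusted p = 0.493 with an estimated correlation). The heat shock call was lost after quantile normalization (0.0577), without LB DMSO replicate 2 (0.0545), without LB amiodarone plus HPbCD replicate 1 (0.0885) and with fry (0.0595), over a range of 0.00137 to 0.493 among all alternatives. Of the 16 hypoxia and glycolysis genes tested, 13 rose, 1 fell and 2 did not pass, 14 within the list (median log2 difference 0.60, adjusted p = 1.46e-09, adjusted p = 0.0107 with an estimated correlation). NDRG1 (9.09 ± 0.421 to 40.8 ± 3.79) rose.

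Of the 25 proliferation genes tested, 18 fell and 7 did not pass, 18 within the list (median log2 difference -0.29, adjusted p = 1.46e-09, adjusted p = 0.211 with an estimated correlation). Among the largest falls were HTRA3 (11.8 ± 1.41 to 2.54 ± 0.28), H19 (31.5 ± 5.47 to 9.89 ± 2.35), CRIP2 (116 ± 3.64 to 48.1 ± 4.07), COL26A1 (28.5 ± 2.06 to 11.7 ± 1.5), CHRDL2 (6.58 ± 1.35 to 2.29 ± 0.445) and LFNG (6 ± 0.445 to 2.09 ± 0.476). The fibrinogen chain genes FGB (204 ± 10.8 to 85.1 ± 11.2), FGA (80.6 ± 5.35 to 35.7 ± 2.56) and FGG (121 ± 7.22 to 56.3 ± 3.98) fell together, and MMP2 (11.6 ± 0.757 to 5.1 ± 0.334) and COL5A1 (12.5 ± 1.77 to 5.57 ± 0.243) fell among matrix genes (adjusted p at most 0.0132 for these). SFTPB (247 ± 15.9 and 249 ± 24.5, adjusted p = 0.966), SFTPC (589.9 ± 66.3 and 597 ± 74.7, adjusted p = 0.955) and SFTPD (300.0 ± 18.2 and 309 ± 35.9, adjusted p = 0.816) did not pass. Nor did ABCA3 (314 ± 35.3 and 278 ± 3.3, adjusted p = 0.128), NAPSA (2.96 ± 0.91 and 1.94 ± 0.573, adjusted p = 0.207) and CDKN1A (182 ± 32.1 and 231 ± 40.8, adjusted p = 0.206). CAV1 (139 ± 14.7 to 106 ± 12.3) fell. The fall was lost for CAV1 without A549 DMSO replicate 1 or LB DMSO replicate 1 or 2 or LB amiodarone plus HPbCD replicate 1 or 3 (adjusted p 0.0265 to 0.147).

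The other 14 lists tested were not called (adjusted p = 0.0611 to 0.965). Median and mean differed in sign for fatty acid oxidation (median 0.03 and mean -0.01) and type II genes (median 0.01 and mean -0.01), and for LXR targets the camera direction was down (median 0.01 and mean 0.07).

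In all 2495 genes changed (1404 higher and 1091 lower), 207 at least 2-fold (174 higher and 33 lower), and 320 and 106 with pseudocounts of 0.1 and 5. The balance turned with mitochondrially encoded genes removed (1296 higher and 1372 lower). The groups did not overlap in 5457 genes (39.1%, against 10% by chance). Of 28 lists 14 were called (13 up and 1 down), 10 with an estimated correlation and 16 with fry. More genes changed here than with amiodarone alone, but the difference between the counts was not tested, and HPbCD and amiodarone cannot be separated without a group given HPbCD alone.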

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

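The tests of this part were chosen after the interferon result was seen, and what each would show was written down only after values were known. A search of 5068 protein-coding genes below the filter but above 0 somewhere, which no comparison used, found 6 whose mean reached 2 TPM in 1 LB group. All 3 libraries of that group lay above every library of the other groups. All 6 genes were in LB amiodarone plus HPbCD, and the differences were not tested. They were MX2 (2.47 ± 0.306 TPM, n = 3, against 0.75 in the highest other library), IFI44L (2.38 ± 0.457, against 0.23), SLAMF7 (2.35 ± 0.545, against 1.27), SLC43A3 (2.15 ± 0.182, against 0.97), DHX58 (2.04 ± 0.0529, against 1.11) and CMPK2 (2.02 ± 0.715, against 0.78). MX2, IFI44L, DHX58 and CMPK2 are known interferon-stimulated genes. The same search found 26 genes in A549 DMSO, which was left out as the control, and 0 in LB DMSO and in LB amiodarone. The 2 TPM limit and the leaving out of A549 were set after values were seen.

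The rise of interferon-stimulated genes with HPbCD was weighed against 2 technical explanations and 1 biological one. Scaling is excluded as the cause, since it moves all genes alike: the median log2 difference of all tested genes was -0.00814, and the smallest of the list over 3 other scalings was 1.88, equal to the original. GC content and transcript length are excluded too, since other genes alike in both did not rise with the list: among the 50 nearest genes of each of the 16 members the highest median was 0.0536. Removing the trend on both, the test chosen first, decides nothing, because the trend was too small (SD 0.0082) to move any gene much. Interferon made by the treated cells could drive the rise, but of 22 interferon genes listed 8 were above 0 anywhere, and the highest mean in LB amiodarone plus HPbCD was 0.463 TPM (IFNE, 0.723 in LB amiodarone). IFNL1, IFNL2, IFNL3 and IFNB1 went the other way, from 0.15, 0.06, 0.083 and 0 TPM to 0.28, 0.2, 0.25 and 0.047 TPM. For 0 of the 22 did all libraries lie above those of LB amiodarone, and none was tested, so this stays open. Whether HPbCD alone or its combination with the drug is needed was not tested.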

How the results depend on the processing

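Most gene results kept their direction and their side of the threshold under the alternatives, while most list calls were lost under at least 1. Of 260 gene results printed as past the threshold 0 reversed, while 13 lost their call in some setting and 19 with some library left out. Printed genes were partly chosen for keeping their call, so these counts understate how many are lost: of all 413 such results the naming rule takes, 60 lost their call in some setting and 81 with some library left out. Of 53 list calls 34 were lost in some setting, mostly with an estimated correlation, and 9 with a library left out. The gene results that reversed were of genes that did not pass, with log2 differences near 0. In LB DMSO against A549 DMSO SREBF1 ran from -0.199 to 0.057 over the libraries left out. For amiodarone CDKN1A ran from -0.017 to 0.253, and for HPbCD over amiodarone CAV1 from -0.129 to 0.071, HMGCS1 from -0.21 to 0.005 and NAPSA from -0.037 to 0.245. For both compounds against LB DMSO SFTPB ran from -0.072 to 0.056, SFTPC from -0.075 to 0.105 and SFTPD from -0.052 to 0.106, with -0.047, -0.089 and -0.03 after quantile normalization. With mitochondrially encoded genes removed SFTPB and SFTPC were at -0.017 and -0.008, and with array weights at -0.007 and -0.001. The cause was not tested. Counts moved more. Genes changed at least 2-fold between LB and A549 DMSO were 396 with a filter at a mean of 5 TPM, which tests fewer genes. With a pseudocount of 5, which shrinks differences of low genes, they were 301 there and 49 for amiodarone. For HPbCD they were 23 (30 with the stricter filter) and for both compounds 106 (320 with pseudocount 0.1). Without 1 library changed genes ran from 628 to 1497 for amiodarone and 280 to 825 for HPbCD. Both peaked without A549 DMSO replicate 2, in neither comparison. Opposite calls were 31 to 113 and the correlation -0.27 to -0.142. Opposite calls were 39 with no filter, 47 without trend and 116 with array weights, and the correlation was -0.257 and -0.1 with pseudocounts of 0.1 and 5, -0.223 with no filter, -0.0843 with the stricter filter and -0.0696 with protein-coding genes only; the cause was not tested. An estimated correlation left 0, 7 and 2 lists in the first 3 comparisons. The labels do not say that replicate numbers pair samples: with the number as a block 4581, 1198, 606 and 2558 genes changed in the 4 comparisons. Under the block ABCA1, CAV1 and SFTPD gained a call for amiodarone and ATF3 and SFTPD for HPbCD over amiodarone, while MTCP1 lost its call there. Samples with the same number correlated at -0.027 to 0.212 after group means were removed, with the own number best in all but 3 of 12 cases, a hint from the data and not the design. Depth is unknown, so its limit on precision could not be given.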

Other observations

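The families and patterns of this part were chosen for tests after the results were seen, and what the tests of a single region and of both surfactant explanations would show was written down only after their values were known. Over 10 families and 40 tests with limma and camera, subunits of the vacuolar ATPase, which acidifies lysosomes, rose with amiodarone: 10 of 19 passed and 0 fell (median log2 difference 0.26, camera adjusted p = 1.15e-08, adjusted p = 0.00794 with an estimated correlation). ATP6V1E1 (108 ± 2.15 to 151 ± 3.99 TPM, adjusted p = 0.000157) and ATP6V1D (89.2 ± 4.99 to 122 ± 3.1 TPM, adjusted p = 0.000343) were examples. Against vehicle 14 of 19 rose with both compounds (median log2 difference 0.41, camera adjusted p = 8.04e-09, adjusted p = 0.00794 with an estimated correlation). Of 40 proteasome genes 10 fell with amiodarone (median log2 difference -0.13, camera adjusted p = 1.5e-07, adjusted p = 0.41 with an estimated correlation), among them PSMG3 (100.5 ± 2.07 to 77.8 ± 1.7 TPM, adjusted p = 0.000464). With HPbCD 8 rose (median log2 difference 0.15, camera adjusted p = 2.15e-12, adjusted p = 0.285 with an estimated correlation), among them PSMC4 (357 ± 17.7 to 437 ± 14.1 TPM, adjusted p = 0.00451). Both rest on the LB amiodarone libraries, and against vehicle 5 rose and 2 fell (median log2 difference 0.01, camera adjusted p = 0.441, adjusted p = 0.882 with an estimated correlation), so the fall and rise could come from that shared group.

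Antigen presentation genes rose with HPbCD beside the interferon-stimulated ones. Of 15 genes of MHC class I presentation 7 rose and 0 fell (median log2 difference 0.42, camera adjusted p = 9.43e-10, adjusted p = 0.115 with an estimated correlation), with HLA-B (15.3 ± 0.48 to 29.5 ± 1.56 TPM, adjusted p = 3.61e-05) and B2M (551 ± 14.6 to 806 ± 30.9 TPM, adjusted p = 0.000136). HLA genes vary between people, so their levels are uncertain. The RNA sensor genes DDX58 (3.6 ± 0.268 to 11.9 ± 1.68 TPM, adjusted p = 2.16e-05) and IFIH1 (1.4 ± 0.458 to 5 ± 0.694 TPM, adjusted p = 0.000881) rose. So did STAT2 (13.6 ± 1.56 to 21.4 ± 1.46 TPM, adjusted p = 0.00451) and IRF1 (18.6 ± 1.57 to 26.9 ± 2.39 TPM, adjusted p = 0.00718). The DNA sensor genes CGAS (8.23 and 9.353 TPM, adjusted p = 0.609) and TMEM173 (3.68 and 5.663 TPM, adjusted p = 0.129) did not pass. Levels of sensor genes do not tell what set off the rise, which was not tested.

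Genes of chromosome 6 were higher in LB DMSO than in A549 DMSO. Of 686 tested 258 rose and 48 fell, with a median log2 difference of 0.216 (1.16-fold) against -0.126 to 0.048 on the 22 other chromosomes. Bias by GC content, length or expression is argued against: with that trend removed 6 lay at 0.253, the next at 0.0568. A single region is excluded, as 9 of 9 windows of 20 Mb lay above every other chromosome. More copies of chromosome 6 could explain it, but no DNA was measured. Extra copies would shift genes of all levels alike, and the medians of 4 equal sets, from low to high expression, were 0.129, 0.172, 0.223 and 0.282. The pseudocount shrinks low genes: with one of 0.1 they were 0.194, 0.189, 0.237 and 0.286. The rest of that slope was not explained. No treatment or group gives a biological explanation to set against it.

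The surfactant genes and ABCA3 of LB DMSO were weighed against 2 explanations. RNA from alveolar type II cells is excluded, since the highest mean of 5 other markers of those cells was 0.317 TPM (LAMP3), while SFTPC was 1860 times that. Introduced copies of a few surfactant genes could give this picture. That stays open, since TPM per gene does not tell an introduced copy from the cell's own gene. The 5 of 9 type II genes that did not pass had a median log2 difference of 0.0704, which decides nothing, as they were chosen for not passing and ran from -0.527 to 0.268.

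Each comparison was repeated with its 6 libraries split 3 and 3 in all 10 ways, too few for a share under 0.05. For LB DMSO against A549 DMSO the real split gave 4525 changed genes, 679 at least 2-fold and 15 lists, and the highest others 1, 1 and 12. For amiodarone against LB DMSO it gave 1204, 85 and 11, and the highest others 1, 1 and 11, so 2 splits reached the list count. For amiodarone plus HPbCD against amiodarone the values were 568, 50 and 13, and 0, 0 and 11. Against LB DMSO they were 2495, 207 and 14, and 1, 1 and 12. Opposite calls were 71 and 0, deciding nothing, as other splits called 0 genes for HPbCD. The correlation of fold changes was -0.165, and with the real split 9 of the 10 were as negative, to -0.415. In all else only the real split was as large.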
